A study of Homo sapiens with 12 samples.

How the data were processed

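RNA was measured by BRB-seq, a barcoded sequencing of the 3′ ends of polyadenylated RNA, in 12 libraries from the human clear cell renal cell carcinoma line 786-O. Per the labels' protocols, 4 lines were grown with doxycycline for 72 hours, with 3 libraries of each: the parental line, and lines carrying doxycycline-inducible shRNAs against HIF2A (the protein of EPAS1; shHIF2A), against JUN, JUNB and JUND (shJUNs), and against YAP1 and WWTR1, the genes of YAP and TAZ (shYAPTAZ). Per the labels' protocols, the derived lines were selected with puromycin, blasticidin or hygromycin depending on how many genes were silenced, and RNA was purified with RNeasy Mini columns. The labels call the replicates technical, so no p-value here measures the spread between independently derived lines. Those of genes and lists rest at most on the spread between these libraries, and those of the chromosome shifts on random sets of genes. No line with a control shRNA was analysed here.

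The deposited file holds raw counts per gene, made by the authors with Trim Galore and STAR on the hg38 genome per the submitters' processing notes. The program that counted, its use of read strands, the annotation release, the versions of the tools and whether molecular identifiers were collapsed are not given in the sources used here; per the file headers, the columns have the layout that featureCounts writes. The deposited table had 62705 lines after its header. The values of 1 gene were broken over 3 lines and shifted out of their columns, and that gene was left out, which gave 62702 genes. Gene symbols came from a table of gene IDs and symbols, which named 62624 of them and left 78 under their IDs. Coordinates (hg38) were taken from the deposited table. Gene types and transcript sequences came from GENCODE release 29.

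Total counts were 2885287, 3603339 and 3559731 in parental replicates 1 to 3, 3526537, 3227893 and 2867807 in shHIF2A, 4469956, 3684052 and 4370700 in shJUNs, and 2272459, 3172106 and 4127139 in shYAPTAZ. The deepest library held 1.97 times the counts of the shallowest. At these depths 3 counts in 1 library equal 0.67 to 1.32 CPM, the edgeR unit of counts scaled to the library size. Between 15145 and 16734 genes had at least 1 count per library. Differences between replicates exceeded counting error: over genes with at least 20 counts, chi-squared per degree of freedom lay between 4.91 and 20.24 in the 12 pairs of replicates. Intervals and floors below cover counting error only.

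Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and 1 robust quasi-likelihood fit with a mean per group covered all 12 libraries. The filter left 12301 genes, and the common dispersion was 0.0628, a coefficient of variation of 25.1%. The 6 comparisons were each knockdown against parental and each pair of knockdowns, and 1 further test asked which genes differed among the 4 groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are mean CPM ± SD over 3 libraries. Where a gene had no count in a group, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts over the group, the ratio is given with its 95% exact binomial (Clopper-Pearson) interval. Counts of paralogs, of antisense genes and of genes that overlap are uncertain, because how shared reads were counted is not given in the sources used here.

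Genes to be named were fixed by a rule: the shRNA targets; in each knockdown against parental the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM, a plain symbol and no overlap between the 3 and 3 libraries; the 4 members with the smallest p of the HIF2A, YAP/TAZ and AP-1 target lists; up to 3 members of any other list called, in the direction of the list; in each direction the 8 genes called in all 3 knockdowns with the largest smallest change; and the 4 largest changes in each direction between knockdowns. This named 114 genes in 226 pairs of gene and comparison. The values of some genes that the rule names are not reported here. Genes outside the rule are named with a statement that they were chosen after their values were seen.

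A set of 24 gene lists was fixed with the rule, before the data were examined: HIF2A targets, glycolysis and hypoxia metabolism, YAP/TAZ targets, AP-1 family members, AP-1 targets, DNA replication and S phase, mitosis, interferon-stimulated genes, p53 targets, cholesterol synthesis, fatty acid synthesis and lipid droplets, the unfolded protein and integrated stress response, oxidative phosphorylation from nuclear genes, mitochondrial genome transcripts, cytosolic ribosomal proteins, replication-dependent histones, NF-kB and inflammatory cytokines, extracellular matrix and mesenchymal genes, actin cytoskeleton and focal adhesion, epithelial junctions and keratins, renal tubule markers, and blood cell, endothelial and neural markers. The shRNA targets were left out of every list. Lists with at least 5 measured members, 21 in number, were tested with camera from limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over 126 tests. Camera was repeated with an estimated correlation, and fry was run beside it. Counts of called members are given as adjusted over all genes tested and as adjusted over the list alone.

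Overlaps between comparisons were set beside the number that independent lists would share (the product of the counts over the genes tested) and beside 2 sets of 40 simulations with 1 set of simulated controls, 1 set with 3 unchanged groups and 1 in which the log2 changes of the called genes were shuffled among genes of like level, in 10 bins, independently for each knockdown. The shift of each of 25 chromosomes was tested against 10000 random gene sets in the 3 comparisons with parental, 75 tests in all, over genes with a mean of at least 5 CPM. The pipeline was tested on simulated data. Changes of 1.5-fold, 2-fold and 4-fold were planted in 67, 67 and 66 genes of simulated counts, where 11515 genes were tested. They were recovered in 9%, 35.8% and 72.7% of those genes. Of 85 genes called there, 7 were unchanged, a share of 8.2%, and no gene was called in an unchanged simulated group. A planted list of 30 genes moved 1.5-fold was called at an adjusted p of 2.2e-12, and none of the 126 tests of lists with no planted change was called. Simulated genes were drawn independently, so this cannot show how often lists of correlated genes are called falsely. In the data the estimated correlation was 0.631 for mitosis and 0.535 for S phase genes.

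Alternatives tried were relative log expression size factors, no filter, a filter at a mean of 10 CPM, the DESeq2 1.42.0 Wald test, limma-voom, a block for the replicate number, a fit on the 6 libraries compared, a fit that was not robust, counts thinned to the shallowest library, each of the 12 libraries left out in turn, a fold change of at least 2-fold, and for lists the estimated correlation and fry. The simulation with planted changes was added after seeing the data. A further 3 alternatives were chosen after seeing the data: parental replicate 1 and shYAPTAZ replicate 1 both left out, because they stood apart in actin and proliferation genes; genes on chromosomes 13, 14 and Y left out; and each chromosome centred on its median. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.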

Results

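Polyadenylated RNA was measured in 12 libraries of 786-O, a clear cell renal cell carcinoma line that lacks working VHL, the protein that marks HIF2A for destruction. The libraries form 4 groups of 3: parental cells, and lines with shRNAs against HIF2A (shHIF2A), against the AP-1 subunits JUN, JUNB and JUND (shJUNs), and against YAP and TAZ (shYAPTAZ), all after 72 hours of doxycycline. Total counts per library ranged from 2885287 to 3603339 in parental cells, from 2867807 to 3526537 in shHIF2A, from 3684052 to 4469956 in shJUNs and from 2272459 to 4127139 in shYAPTAZ. Transcripts of the mitochondrial genome took 6.33% to 9.37% of the counts of a library. Levels below are mean CPM, a gene's counts scaled to the library size, ± SD with n = 3 libraries in each group. A difference among the 4 groups was called for 4759 of the 12301 genes tested.

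In each knockdown the mRNAs of its own targets were lower than in parental cells, though for JUNB the libraries overlapped. Some targets of one knockdown also moved in others, JUN about as far in shHIF2A as in shJUNs. EPAS1, which encodes HIF2A (ENSG00000116016, chromosome 2, 46293667 to 46386697, hg38), was 203 ± 59.6 CPM in parental cells and 15.97 ± 3.58 CPM in shHIF2A, 12.7-fold lower (adjusted p = 6.38e-07). It was 37.1 ± 1.20 CPM in shJUNs, 5.47-fold lower (adjusted p = 1.78e-05), and 114 ± 56.8 CPM in shYAPTAZ, 1.8-fold lower (adjusted p = 0.0361). The shYAPTAZ libraries overlapped the parental ones for EPAS1, and the call ended without parental replicate 1 (adjusted p = 0.173), parental replicate 2 (0.068), shYAPTAZ replicate 2 (0.101) or shYAPTAZ replicate 3 (0.0957), with thinned counts (0.0796) and in a fit of those 6 libraries alone (0.0842).

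JUND (ENSG00000130522, chromosome 19, 18279694 to 18281622) fell from 355 ± 40.98 CPM to 38.6 ± 3.998 CPM in shJUNs, 9.2-fold (adjusted p = 1.41e-11). It also fell in shHIF2A, 1.61-fold to 220.1 ± 43.2 CPM (adjusted p = 0.00312), and in shYAPTAZ, 2.09-fold to 170 ± 4.18 CPM (adjusted p = 2.71e-05). JUN (ENSG00000177606, chromosome 1, 58776845 to 58784048) fell from 153 ± 17.7 CPM to 85.6 ± 7.43 CPM in shJUNs, 1.79-fold (adjusted p = 0.00215), and to 80.2 ± 0.583 CPM in shHIF2A, 1.91-fold (adjusted p = 0.00103). JUN was 155 ± 40.4 CPM in shYAPTAZ (adjusted p = 0.951). JUNB (ENSG00000171223, chromosome 19, 12791486 to 12793315) was 192 ± 86.4 CPM in parental cells, 113 ± 10.9 CPM in shJUNs (adjusted p = 0.034), 156 ± 23.1 CPM in shHIF2A (0.414) and 197 ± 19.8 CPM in shYAPTAZ (0.942). Its fall in shJUNs rested on overlapping libraries. The call ended without parental replicate 2 (adjusted p = 0.113), parental replicate 3 (0.2) or shJUNs replicates 1 (0.118), 2 (0.102) or 3 (0.0619), with limma-voom (0.0537) and in a fit of 6 libraries (0.0506), and JUNB passed in shHIF2A without parental replicate 1 (0.0154).

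YAP1 (ENSG00000137693, chromosome 11, 102110447 to 102233424) fell from 65.4 ± 6.61 CPM to 14.1 ± 6.65 CPM in shYAPTAZ, 4.78-fold (adjusted p = 1.2e-06), and passed the test in neither shHIF2A (0.143) nor shJUNs (0.617). WWTR1, the gene of TAZ (ENSG00000018408, chromosome 3, 149517235 to 149736714), fell from 311 ± 66.1 CPM to 153 ± 14.6 CPM in shYAPTAZ, 2.04-fold (adjusted p = 2.23e-05). It rose in shHIF2A, 1.62-fold to 504 ± 25.9 CPM (adjusted p = 0.00181), and in shJUNs, 1.42-fold to 441 ± 28.8 CPM (adjusted p = 0.0169). The rise in shJUNs was lost without parental replicate 1 (adjusted p = 0.0846), shJUNs replicate 1 (0.07) or shJUNs replicate 2 (0.0687).

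**Figure D1:**
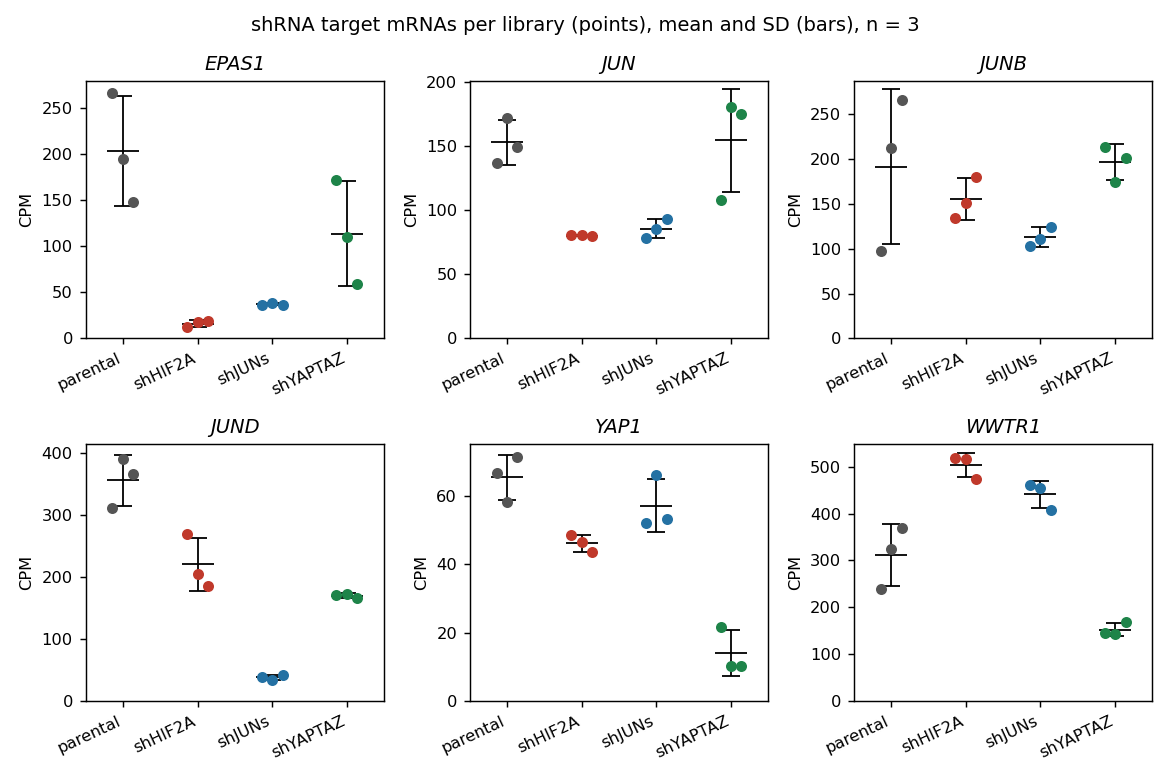
CPM, the counts scaled to library size, of the shRNA targets EPAS1, JUN, JUNB, JUND, YAP1 and WWTR1 in each of the 12 libraries, by group, with points for libraries, a mark for the mean and error bars for the SD (n = 3). EPAS1 lies at 203 CPM in parental cells, 15.97 in shHIF2A, 37.1 in shJUNs and 114 in shYAPTAZ.

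The comparison of shHIF2A with parental cells asks which transcripts depend on HIF2A. Since no line with a control shRNA was analysed, effects of a knockdown cannot be told from other differences between the lines. This limit holds for each comparison with parental cells. Known HIF2A targets fell. SLC2A1, the glucose transporter GLUT1 (ENSG00000117394, chromosome 1, 42925353 to 42958893), fell 7.33-fold from 1573 ± 236 CPM to 215 ± 4.85 CPM (adjusted p = 5.51e-12). VEGFA, the angiogenic growth factor (ENSG00000112715, chromosome 6, 43770184 to 43786487), fell 6.21-fold from 315 ± 125 CPM to 50.7 ± 6.28 CPM (adjusted p = 7.1e-07). CCND1, which encodes cyclin D1 (ENSG00000110092, chromosome 11, 69641156 to 69654474), fell 34.5-fold from 723 ± 219 CPM to 21.1 ± 11.5 CPM (adjusted p = 1.86e-08). In all, edgeR called 1211 genes higher and 1082 lower, of which 576 and 634 changed at least 2-fold. Without parental replicate 1 the genes higher numbered 772. The libraries did not overlap for 36.1% of genes tested, against 10% by chance.

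Of the 27 measured HIF2A targets, 17 fell and 0 rose by edgeR, adjusted over all genes and equally adjusted over the list alone, with a median log2 change of -1.42 (camera adjusted p = 1.26e-08). BHLHE40, a transcriptional repressor induced by hypoxia, was the other member among the 4 with the smallest p, and fell 3.77-fold from 214 ± 10.4 CPM to 56.8 ± 16.2 CPM. The adjusted p of the list was 0.188 with an estimated correlation, and no list call in any of the 6 comparisons held with that setting. Among 25 genes of glycolysis and hypoxia metabolism 8 fell and 1 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.0227, and adjusted p = 0.188 with an estimated correlation). ENO2 fell 6.54-fold, PFKP 2.01-fold and LDHA 1.75-fold. All 3 encode glycolytic enzymes.

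**Figure D2:**
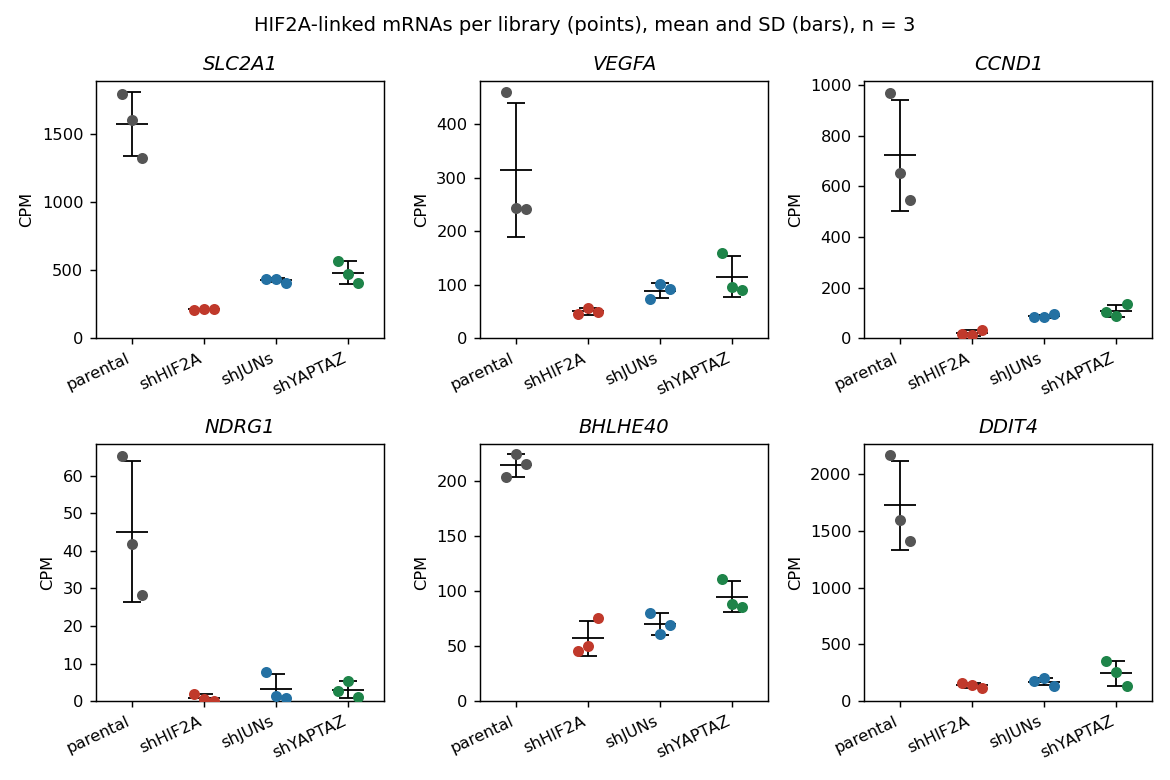
CPM, the counts scaled to library size, of SLC2A1, VEGFA, CCND1, NDRG1, BHLHE40 and DDIT4 in each of the 12 libraries, by group, with points for libraries, a mark for the mean and error bars for the SD (n = 3). SLC2A1 lies at 1573 CPM in parental cells and at 215, 428 and 483 CPM in shHIF2A, shJUNs and shYAPTAZ.

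The largest falls in shHIF2A outside the lists included MYEOV (ENSG00000172927, chromosome 11, 69294151 to 69341682), a neighbour of CCND1, which went from 126 ± 19.5 CPM to 1.66 ± 1.47 CPM, 77.3-fold (adjusted p = 5.04e-08). FZD8, a Wnt receptor, fell 50.8-fold and NDRG1 46.6-fold (adjusted p = 1.75e-06 and 0.00022), and the antisense transcript LUCAT1 fell 17.5-fold. The largest rises were CEMIP, a hyaluronan-degrading protein (ENSG00000103888, chromosome 15, 80779343 to 80951776), from 0.398 ± 0.146 CPM to 54.9 ± 7.52 CPM, 126-fold (adjusted p = 2.21e-11), GASK1B (32.1-fold), MIR30A, the locus of a microRNA (37.3-fold), and PLPP3 (29.1-fold). IFI44L had 3 counts over the parental libraries and 106 over shHIF2A, a ratio of 37 (95% interval 12.3 to 182). SATB1 had no parental count and rose at least 3.84-fold (adjusted p = 0.0118), a call lost with limma-voom (0.162) and without shHIF2A replicate 2 (0.0538).

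Camera with the preset correlation called the mitosis and S phase lists lower in shHIF2A. Of 30 mitosis genes 11 fell and 0 rose by edgeR (18 and 0 adjusted over the list alone, camera adjusted p = 1.27e-06, and adjusted p = 0.536 with an estimated correlation). Among them TOP2A, a topoisomerase, fell 2.14-fold from 558 ± 46.7 CPM to 261 ± 72.0 CPM, CCNB2 (2.34-fold) and CENPF (2.23-fold). Of 30 genes of DNA replication and S phase 7 fell and 0 rose by edgeR (9 and 0 adjusted over the list alone, camera adjusted p = 0.00481, and adjusted p = 0.642 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell 2.56-fold and RFC4, of the clamp loader, 2.29-fold, while E2F2 had 47 parental counts and 3 in shHIF2A, a ratio of 15 (interval 4.82 to 75.1). Libraries of the same group differed in these genes: the mean centred log2 CPM of the S phase list was -0.76, -0.57 and 0.12 in shHIF2A replicates 1, 2 and 3, and -0.21, 0.33 and 0.29 in the parental ones. The S phase call was lost without shHIF2A replicate 1 (adjusted p = 0.0648) and by fry (0.201), and the E2F2 call without shHIF2A replicate 1 (0.0507).

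The list of the unfolded protein and integrated stress response was called lower as well. Of 25 members of that list 12 fell and 1 rose (13 and 3 adjusted over the list alone, camera adjusted p = 0.00401, and adjusted p = 0.215 with an estimated correlation). TRIB3 fell 7.18-fold from 343 ± 118 CPM to 47.7 ± 1.86 CPM, PSAT1, an enzyme of serine synthesis, 4.34-fold, and DDIT3, the transcription factor CHOP, 4.02-fold. Among 11 AP-1 family members 5 fell and 0 rose by edgeR with either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.188 with an estimated correlation). MAFF fell 6.01-fold, MAF 2.2-fold and ATF2 1.8-fold. The ATF2 call was lost without parental replicate 1 (0.0605) or shHIF2A replicate 2 (0.0572).

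Lists of respiration, interferon response, cytoskeleton, matrix and sterol synthesis genes were called higher in shHIF2A by camera with the preset correlation, though most members did not pass by themselves. Of 41 nuclear genes of oxidative phosphorylation 15 rose and 0 fell by edgeR (16 and 0 adjusted over the list alone, camera adjusted p = 0.000679, and adjusted p = 0.362 with an estimated correlation). ATP5MC1 rose 2.05-fold and UQCRB 1.65-fold. Mitochondrial genome transcripts, 13 in number, had 5 higher and were not called as a list (0.105). Their share of counts was 9.37%, 8.49% and 7.2% in the shHIF2A libraries and 7.64%, 7.29% and 6.91% in the parental ones. Of 28 interferon-stimulated genes 8 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.0038, and adjusted p = 0.215 with an estimated correlation). ISG15 rose 3.83-fold from 32.1 ± 11.9 CPM to 124 ± 2.11 CPM.

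Of 29 actin cytoskeleton and focal adhesion genes 12 rose and 4 fell in shHIF2A (15 and 4 adjusted over the list alone, camera adjusted p = 0.0202, and adjusted p = 0.575 with an estimated correlation). MYL9, a myosin light chain, was 3.87-fold higher. Parental replicate 1 had the lowest mean centred log2 CPM of this list among all libraries, -0.49, and without it the call ended (0.0539). Of 29 matrix and mesenchymal genes 10 rose and 2 fell (12 and 6 adjusted over the list alone, camera adjusted p = 0.0466, and adjusted p = 0.462 with an estimated correlation). TNC, the matrix protein tenascin C (ENSG00000041982, chromosome 9, 115019575 to 115118207), rose 8.74-fold from 7.90 ± 0.996 CPM to 69.4 ± 13.5 CPM, COL4A1 2.83-fold and FN1, fibronectin, 2.11-fold. The matrix call ended without parental replicate 2 (0.052), parental replicate 3 (0.054), shHIF2A replicate 1 (0.0676), shJUNs replicate 2 (0.0509), shYAPTAZ replicate 1 (0.0557) or shYAPTAZ replicate 3 (0.0537). It also ended with the filter at 10 CPM (0.167) and without chromosomes 13, 14 and Y (0.174). Of 22 cholesterol synthesis genes 5 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0202, and adjusted p = 0.583 with an estimated correlation). HMGCS1 rose 2.75-fold. This call was lost without parental replicate 1 (0.159), shHIF2A replicate 1 (0.0506) and by fry (0.061).

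The remaining lists were not called in shHIF2A. Among 21 YAP/TAZ targets 6 fell and 4 rose (camera adjusted p = 0.0934, fry 0.0044). AMOTL2 fell 2.37-fold and IGFBP3, which the HIF2A list also holds, 3.38-fold, while CCDC80 rose 2.54-fold and CRIM1 2.06-fold. Among 26 AP-1 targets 5 fell and 3 rose (camera adjusted p = 0.155), with DUSP1, a phosphatase of MAP kinases, 3.81-fold lower, CD44 2.11-fold lower and UPP1 2.21-fold lower. Camera gave adjusted p-values of 0.449 for 26 p53 targets, 0.306 for 18 genes of fatty acid synthesis and lipid droplets, 0.707 for 48 ribosomal proteins, 0.306 for 6 histones, 0.323 for 14 epithelial genes and 0.256 for 8 renal tubule markers. Epithelial genes passed by fry as higher (0.013). For 22 NF-kB and cytokine genes (0.758) the median of -0.05 and the mean of -0.02 were negative while camera gave the direction up.

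The comparison of shJUNs with parental cells asks which transcripts depend on AP-1, and has the limit given above for shHIF2A. HIF2A targets fell here too. SLC2A1 fell 3.68-fold to 428 ± 15.1 CPM (adjusted p = 1.85e-09), CCND1 8.26-fold to 87.4 ± 6.64 CPM (1.18e-06), VEGFA 3.53-fold to 89.2 ± 13.7 CPM (2.79e-05) and BHLHE40 3.06-fold to 69.9 ± 9.90 CPM (2.6e-06). Of the 27 HIF2A targets 14 fell and 2 rose (14 and 3 adjusted over the list alone), with a median log2 change of -1.18 (camera adjusted p = 4.08e-05, and adjusted p = 0.188 with an estimated correlation). The largest rise among named epithelial genes was KRT19, a keratin of simple epithelia (ENSG00000171345, chromosome 17, 41523617 to 41528308), from 7.86 ± 1.19 CPM to 305 ± 32.7 CPM, 38.7-fold (adjusted p = 5.13e-13). In all, 1271 genes were called higher and 1099 lower, of which 706 and 547 changed at least 2-fold, and the libraries did not overlap for 39.5% of genes against 10% by chance. Without shJUNs replicate 3 the counts were 846 and 672.

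Several genes were silent or nearly so in shJUNs. LEF1, a transcription factor of the Wnt pathway, went from 15.1 ± 2.94 CPM to no count, at least 64.3-fold lower (adjusted p = 3.87e-07), and AUTS2 to no count, at least 23.9-fold lower. IGFL3 had 385 parental counts and 1 in shJUNs, a ratio of 492 (interval 87.8 to 19500), and CHST9 had 259 and 3, a ratio of 110 (37.3 to 538). SRGN, a proteoglycan core protein, fell 49.8-fold from 25.1 ± 7.16 CPM and ACKR3, a chemokine receptor, 42.7-fold from 89.2 ± 27.4 CPM. In the other direction, SATB1, a chromatin organiser (ENSG00000182568, chromosome 3, 18345377 to 18445621), reached 16.9 ± 3.45 CPM from no count, at least 55.6-fold higher. CENPV had 332 counts against 1, a ratio of 260 (46.3 to 10300), and PAPLN, which lies on chromosome 14, 332 against 3, a ratio of 86.6 (29.4 to 422). CHRDL1, a BMP antagonist, rose 71.5-fold to 45.5 ± 4.16 CPM (adjusted p = 7.1e-10).

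Lists of structural genes were called higher in shJUNs. Of 29 actin and adhesion genes 15 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.000318, and adjusted p = 0.369 with an estimated correlation). MYL9 was 6.35-fold and LIMA1 5.7-fold higher. Of 29 matrix genes 10 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.00291, and adjusted p = 0.227 with an estimated correlation). TNC was 30.3-fold higher at 241 ± 16.9 CPM and COL5A2 18-fold. Among 14 epithelial genes 6 rose and 0 fell by edgeR, over all genes and adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.188 with an estimated correlation). KRT18 rose 3.49-fold and KRT8 3.37-fold besides KRT19. Interferon-stimulated genes had 7 members higher and 0 lower by edgeR (8 and 0 adjusted over the list alone, camera adjusted p = 0.0384, and adjusted p = 0.395 with an estimated correlation). IFI27, on chromosome 14, rose 23.4-fold to 82.4 ± 1.93 CPM, IFI44L by a ratio of 50.3 (17 to 246) and ISG15 3.8-fold. The interferon call ended without parental replicate 1 (0.0539), parental replicate 3 (0.0506), shHIF2A replicate 1 (0.0561), shJUNs replicate 2 (0.0604) or shJUNs replicate 3 (0.0558), and without chromosomes 13, 14 and Y (0.0527). Oxidative phosphorylation genes had 7 members higher and 0 lower by edgeR (9 and 0 adjusted over the list alone, camera adjusted p = 0.0264, and adjusted p = 0.575 with an estimated correlation). The call was lost without parental replicate 1 (0.169).

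The mitosis, ribosomal protein and cholesterol synthesis lists were called lower in shJUNs by camera with the preset correlation, though most members did not pass by themselves. Of 30 mitosis genes 12 fell and 0 rose by edgeR (13 and 0 adjusted over the list alone, camera adjusted p = 9.06e-05, and adjusted p = 0.583 with an estimated correlation). CCNB2 fell 2.18-fold and CENPF 1.93-fold, and the list call was lost by fry (0.109). Of 48 ribosomal protein genes 12 fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 0.00281, and adjusted p = 0.581 with an estimated correlation), RPLP1 1.65-fold. Of 22 cholesterol genes 8 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.0145, and adjusted p = 0.575 with an estimated correlation). INSIG1 was 2.27-fold lower. The call was lost without parental replicate 3 (0.132) and by fry (0.0798).

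The lists of AP-1 family members and YAP/TAZ targets were called lower in shJUNs, and AP-1 targets were not called. Among 11 AP-1 family members 4 fell and 0 rose by edgeR with either adjustment, adjusted over the list alone too (camera adjusted p = 0.019, and adjusted p = 0.188 with an estimated correlation). MAFF fell 11.9-fold and ATF3 3.43-fold. Among 26 AP-1 targets 4 rose and 4 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.891), with DUSP1 4.51-fold lower and SPHK1, a lipid kinase, 4.56-fold and HMOX1, heme oxygenase, 2.63-fold higher. Of 21 YAP/TAZ targets 6 fell and 1 rose, as also adjusted over the list alone (camera adjusted p = 0.0264, and adjusted p = 0.188 with an estimated correlation). AMOTL2 was 2.58-fold, LATS2 2.32-fold and IGFBP3 2.29-fold lower, and CRIM1 2.34-fold higher. The AP-1 family call was lost without shJUNs replicate 1 (0.0533). The YAP/TAZ call was lost without parental replicate 3 (0.0561), without chromosomes 13, 14 and Y (0.0667) and with each chromosome centred (0.0539).

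Lists not called in shJUNs were glycolysis (3 higher, 8 lower, camera adjusted p = 0.395), fatty acid synthesis (0.25), the unfolded protein and integrated stress response (0.105), mitochondrial genome transcripts (0.17), histones (0.515), NF-kB and cytokines (0.105) and renal tubule markers (0.571). Glycolysis (0.0349) and the stress response (0.0074) passed by fry as lower. The S phase list (0.908) had a median of -0.12, a mean of 0.05 and a camera direction of down, and the p53 targets (0.771) had a median of -0.09, a mean of 0.11 and a camera direction of down.

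The comparison of shYAPTAZ with parental cells asks which transcripts depend on YAP and TAZ, but cannot tell these from other differences between the lines. By camera with the preset correlation its strongest list was p53 targets, of which 18 of 26 fell and 1 rose (18 and 2 adjusted over the list alone), with a median log2 change of -1.43 (camera adjusted p = 1.27e-06, and adjusted p = 0.188 with an estimated correlation). Fry ranked YAP/TAZ targets (adjusted p = 6.78e-05) and matrix genes (9.62e-05) before p53 targets (0.000227). CDKN1A, the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687337), fell 9.34-fold from 294 ± 109 CPM to 31.2 ± 3.85 CPM (adjusted p = 5.58e-10), and GDF15, a secreted stress hormone (ENSG00000130513, chromosome 19, 18374731 to 18389176), fell 36.3-fold from 297 ± 118 CPM to 8.13 ± 0.166 CPM (adjusted p = 2.86e-11). Both also lay under the parental mean in the other knockdowns. GDF15 ranged from 41.5 to 56.4 CPM in the shHIF2A libraries and from 42.7 to 70.2 CPM in shJUNs. CDKN1A ranged from 139 to 187 CPM in shHIF2A and from 154 to 168.5 CPM in shJUNs. Of the p53 targets, 7 fell and 3 rose in shHIF2A, and 5 fell and 2 rose in shJUNs. HIF2A targets fell again: SLC2A1 3.26-fold to 483 ± 81.9 CPM (adjusted p = 3.28e-09) and CCND1 6.56-fold to 110 ± 23.5 CPM (2.2e-06). In all, 1599 genes were called higher and 1514 lower, of which 982 and 854 changed at least 2-fold, and the libraries did not overlap for 36.2% of genes against 10% by chance.

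Of the 27 HIF2A targets 17 fell and 3 rose, as also adjusted over the list alone, with a median log2 change of -1.42 (camera adjusted p = 0.000308, and adjusted p = 0.215 with an estimated correlation). SCARB1, a lipoprotein receptor, fell 3.54-fold and IGFBP3 4.03-fold. Of 21 YAP/TAZ targets 11 fell and 4 rose, as also adjusted over the list alone (camera adjusted p = 0.00838, and adjusted p = 0.188 with an estimated correlation). AMOTL2 fell 4.91-fold to 57.1 ± 11.4 CPM, LATS2, a kinase of the Hippo pathway, 4.49-fold, and AXL, a receptor kinase, 2.22-fold. Of 3 much used YAP/TAZ targets, chosen after their values were seen, ANKRD1 fell 4.39-fold in shYAPTAZ (adjusted p = 0.0034) and CCN1 3.1-fold (0.0192, with overlapping libraries), while CCN2 rose 2.54-fold (0.00769, with overlapping libraries). Among AP-1 family members 5 of 11 fell and 0 rose by edgeR with either adjustment, adjusted over the list alone too (camera adjusted p = 0.0227, and adjusted p = 0.195 with an estimated correlation). ATF3 fell 6.35-fold. Of 26 AP-1 targets 6 rose and 3 fell (camera adjusted p = 0.574), SPHK1 3.16-fold higher and DUSP1 5.37-fold and UPP1 2.69-fold lower. Of 25 stress response genes 12 fell and 5 rose (12 and 7 adjusted over the list alone, camera adjusted p = 0.0264, and adjusted p = 0.362 with an estimated correlation). ATF4, its main transcription factor, fell 2.54-fold and DDIT3 4.84-fold. The call was lost without parental replicate 1 (0.06).

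Lists of matrix and cytoskeleton genes were called higher in shYAPTAZ. Of 29 matrix genes 12 rose and 3 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.00291, and adjusted p = 0.227 with an estimated correlation). TNC rose 31.1-fold to 247 ± 33.3 CPM, COL6A3, a collagen chain, 19.4-fold to 120 ± 18.2 CPM and FN1 3.12-fold to 1531 ± 144 CPM. Of 29 actin genes 16 rose and 5 fell (19 and 5 adjusted over the list alone, camera adjusted p = 0.00783, and adjusted p = 0.536 with an estimated correlation). MYL9 rose 3.3-fold and ACTN1, on chromosome 14, 2.57-fold. The mean centred log2 CPM of the actin list was -0.08 in shYAPTAZ replicate 1 and 0.11 and 0.2 in replicates 2 and 3.

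Some genes were switched on or off in shYAPTAZ. MGMT, a DNA repair protein, fell 62.2-fold from 41.9 ± 6.998 CPM to 0.701 ± 0.399 CPM (adjusted p = 4.66e-10) and MYEOV 88.4-fold. SHISA2 and SLC16A4 had no count there, at least 65.5-fold and 44.2-fold lower, and the kinase gene SYK had 262 parental counts against 3, a ratio of 83.2 (28.2 to 406). SATB1 rose at least 131-fold to 43.2 ± 19.7 CPM. Ratios were 474 (131 to 3920) for PTN, a secreted growth factor, 384 (68.5 to 15200) for ENTPD3, 381 (67.9 to 15100) for PDPN, podoplanin, and 294 (80.9 to 2430) for KCNAB1. CHRDL1 rose 151-fold to 96.3 ± 26.6 CPM (adjusted p = 1.2e-11).

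Expression also shifted by chromosome. The 343 genes of chromosome 14 with at least 5 CPM had a median log2 change of 0.87 in shYAPTAZ, a 1.83-fold rise with 86.3% of them higher, 0.4 in shJUNs (1.32-fold, 78.1% higher) and 0 in shHIF2A. In shYAPTAZ the 190 genes of chromosome 13 had a median of -0.52 and the 11 of chromosome Y a median of -1.02. Chromosomes 15, 16 and 22 had medians of -0.34, 0.34 and 0.31 in shJUNs and -0.29, 0.32 and 0.26 in shYAPTAZ. Chromosome 12 had a median of 0.28 in shJUNs and chromosome 6 one of 0.32 in shYAPTAZ. The permutation p of these shifts in shYAPTAZ and shJUNs named here was 1e-04, the smallest that 10000 random sets can give (adjusted p = 0.000417). It treats genes as independent and does not measure the spread between libraries. Further chromosomes passed with smaller medians, and in shHIF2A chromosome 15 alone passed (-0.14, adjusted p = 0.0017). LATS2 and SHISA2 lie on chromosome 13.

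**Figure D3:**
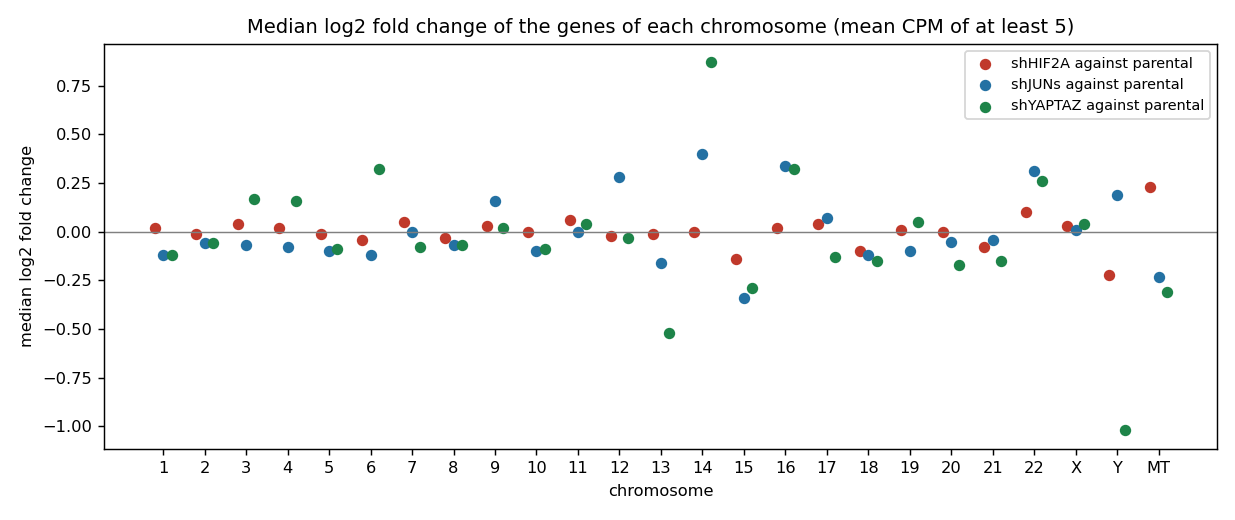
Median log2 change of the genes of each chromosome against parental cells in shHIF2A, shJUNs and shYAPTAZ, 1 point per chromosome and knockdown. Chromosome 14 lies at 0.87 in shYAPTAZ, 0.4 in shJUNs and 0 in shHIF2A.

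Lists not called in shYAPTAZ were mitosis (1 higher, 6 lower, camera adjusted p = 0.232), interferon-stimulated genes (0.497), cholesterol synthesis (0.497), fatty acid synthesis (0.303), oxidative phosphorylation (0.22), mitochondrial genome transcripts (1 higher, 7 lower, 0.0555), ribosomal proteins (0.278), histones (0.515), NF-kB and cytokines (0.592), epithelial genes (0.256) and renal tubule markers (0.361). Mitochondrial genome transcripts (0.0291) passed by fry as lower and epithelial genes (0.00582) as higher. Glycolysis genes (0.845) had a median of 0.18, a mean of -0.02 and a camera direction of up, and S phase genes (0.601) a median of 0.07, a mean of -0.03 and a camera direction of down.

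**Figure D4:**
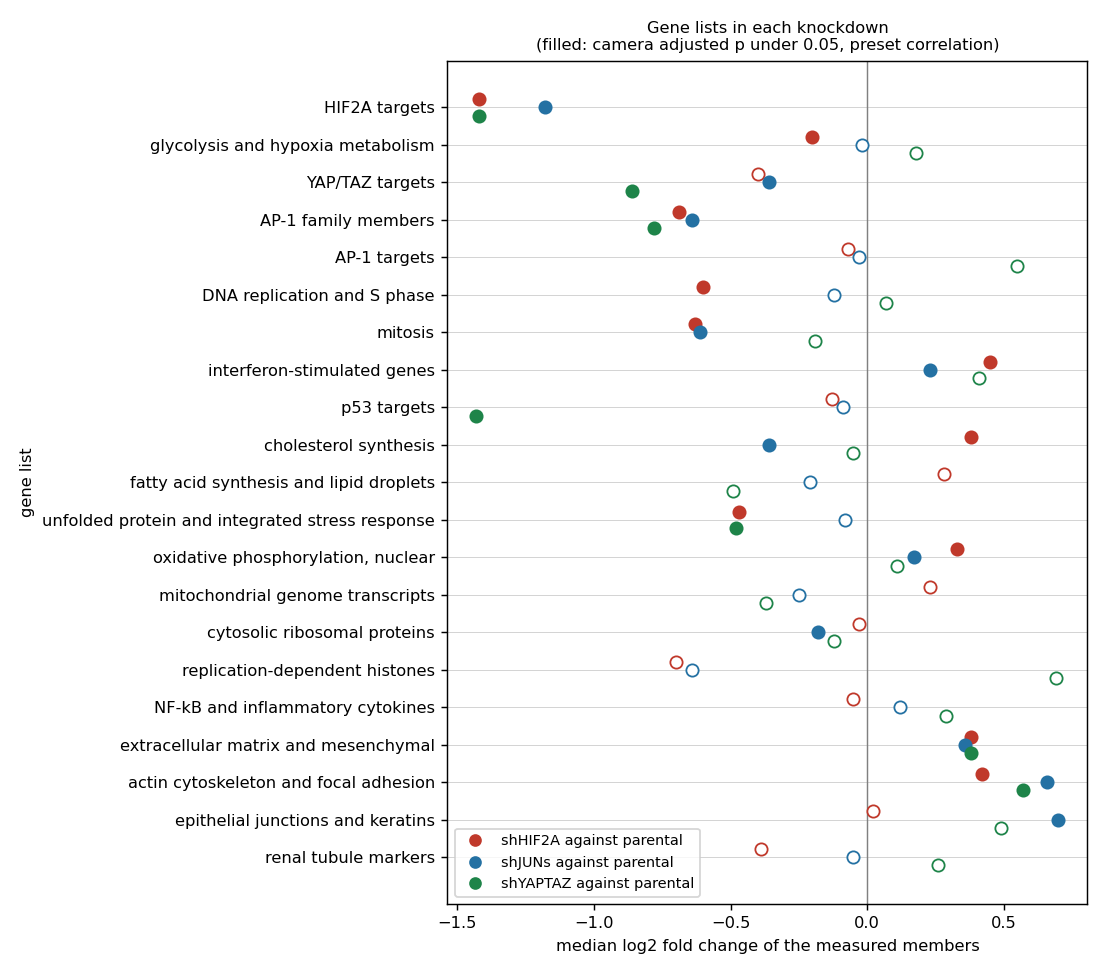
Median log2 change against parental cells of the measured members of each of 21 gene lists, 1 point per list and knockdown, filled where camera called the list with the preset correlation. HIF2A targets lie at -1.42 in shHIF2A, -1.18 in shJUNs and -1.42 in shYAPTAZ, and p53 targets at -1.43 in shYAPTAZ.

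The title of the series asks whether HIF2A, AP-1 and YAP/TAZ act on the same transcripts, and many genes changed in more than 1 knockdown. Of the genes lower in shHIF2A, 545 (50.4%) were also lower in shJUNs and 525 (48.5%) in shYAPTAZ, 554 were lower in both shJUNs and shYAPTAZ, and 351 were lower in all 3. Independent lists would share 96.7, 133.2, 135.3 and 11.9 genes. For rises the counts were 636, 600 and 695 for the pairs and 391 for all 3, against 125.1, 157.4, 165.2 and 16.3. The largest smallest falls were those of CCND1, MYEOV, NDRG1, FZD8, DEPP1, DDIT4, FAM149A and IGFL3. DDIT4, an inhibitor of mTORC1 signalling (ENSG00000168209, chromosome 10, 72273919 to 72276036), was 1724 ± 393 CPM in parental cells and fell 12.4-fold, 10-fold and 7.05-fold in shHIF2A, shJUNs and shYAPTAZ. DEPP1 fell 16-fold, 15.7-fold and 8.6-fold, and NDRG1 (ENSG00000104419, chromosome 8, 133237175 to 133302022) 46.6-fold, 13.2-fold and 15.1-fold. The matching rises were those of CEMIP (126-fold, 79.5-fold and 143-fold), MIR30A (37.3-fold, 53.5-fold and 91.2-fold), GASK1B (32.1-fold, 22-fold and 14.8-fold), KCNK3, a potassium channel (13.5-fold, 14.6-fold and 24.2-fold), SEMA3A, a guidance factor (12.2-fold, 31.2-fold and 13.9-fold), PLPP3, IFI44L and SATB1.

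All 3 comparisons use the same 3 parental libraries, which cannot be split between them, so part of the excess may come from the shared controls. In 40 simulations with the observed changes planted independently in each knockdown and 1 shared set of controls, the genes lower in all 3 averaged 8.6 and those higher 15.2, 1.92 and 1.91 times the numbers that independent lists of that size would share. The observed ratios were 29.5 and 24. For pairs of knockdowns the simulated ratios lay between 1.22 and 1.32, and the observed ones between 3.8 and 5.6. Across genes, which are not independent replicates, log2 changes in shHIF2A correlated with those in shJUNs at r = 0.628, against 0.511 in 40 simulations of unchanged groups with shared controls, with a covariance of 0.603 against 0.12. For shHIF2A and shYAPTAZ r was 0.525 against 0.495 and the covariance 0.611 against 0.12, and for shJUNs and shYAPTAZ r was 0.583 against 0.51 and the covariance 0.744 against 0.12. The simulated groups held no changes, so their r came from noise alone. It cannot say what share of the observed r the shared controls made. The covariance, which is not divided by the spread of the changes, is the value to compare. Calls in opposite directions numbered 23, 63 and 54 for the 3 pairs in this order, where independent lists would give 220, 289.7 and 299.3. Left out in turn, 1 library took the genes lower in all 3 to between 227 and 391 and those higher in all 3 to between 240 and 436. The lowest values, 227 and 240, came without parental replicate 1. Without that library the falls shared by shHIF2A and shJUNs, by shHIF2A and shYAPTAZ and by shJUNs and shYAPTAZ numbered 360, 335 and 363, and the rises shared by shHIF2A with shJUNs and with shYAPTAZ 385 and 380.

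**Figure D5:**
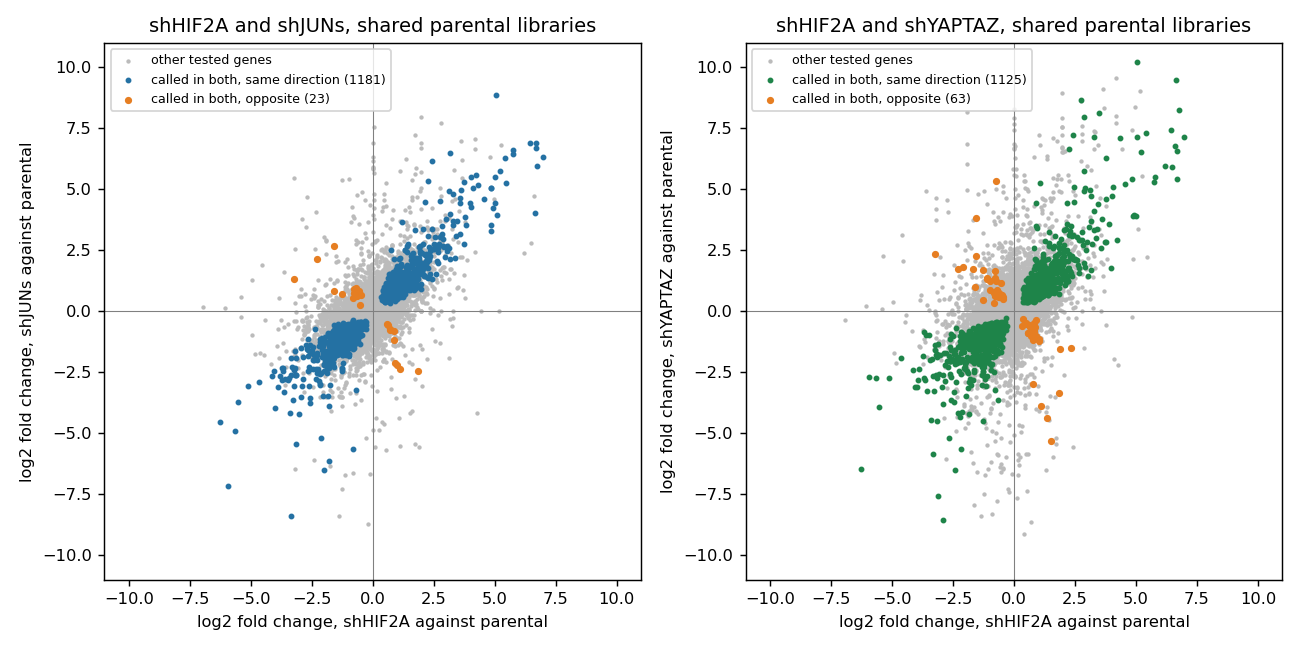
Log2 change against parental cells in shHIF2A (x axis) and in shJUNs or shYAPTAZ (y axis), 1 point per gene tested. Genes called in both knockdowns changed in the same direction in 1181 cases and in opposite directions in 23 for shJUNs, and in 1125 and 63 for shYAPTAZ.

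The comparison of shJUNs with shHIF2A asks where the effects of these knockdowns differ. Cholesterol synthesis genes differed most by median and by camera with the preset correlation: 8 of 22 were lower in shJUNs and 0 higher by edgeR (13 and 0 adjusted over the list alone), with a median log2 difference of -0.72 (camera adjusted p = 1.26e-08, and adjusted p = 0.208 with an estimated correlation). Fry ranked epithelial genes (adjusted p = 0.000101) and glycolysis (0.000463) before cholesterol synthesis (0.00305). HIF2A targets lay higher in shJUNs by a median of 0.57, with 4 of 27 called higher and 0 lower by edgeR (12 and 0 adjusted over the list alone, camera adjusted p = 0.000797, and adjusted p = 0.253 with an estimated correlation). EPAS1 was 2.33-fold higher (adjusted p = 0.029), a call that ended without each of the 6 libraries in turn (0.0585 to 0.121), with limma-voom (0.0927) and with thinned counts (0.12). LAYN, a hyaluronan receptor, was 73.5 ± 6.10 CPM against 0.841 ± 0.461 CPM (83.9-fold higher, adjusted p = 1.61e-09), ALDH2, an aldehyde dehydrogenase, 117 ± 8.86 CPM against 2.55 ± 3.83 CPM (43.1-fold), RHOF 35.6-fold higher and CENPV higher by a ratio of 248 (44.2 to 9830). LEF1 and AUTS2 were at least 56.6-fold and 9.81-fold lower, CHST9 lower by a ratio of 66 (22.2 to 324) and TMEM98 33.8-fold lower.

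Other lists called higher in shJUNs than in shHIF2A were S phase (median 0.49, camera adjusted p = 0.000679, and adjusted p = 0.611 with an estimated correlation), epithelial genes (0.5, 0.0251, and adjusted p = 0.188 with an estimated correlation), actin genes (0.24, 0.0264, and adjusted p = 0.583 with an estimated correlation), glycolysis (0.25, 0.0283, and adjusted p = 0.188 with an estimated correlation) and AP-1 targets (0.36, 0.0408, and adjusted p = 0.611 with an estimated correlation). Lists called lower were mitochondrial genome transcripts (-0.44, 0.000679, and adjusted p = 0.362 with an estimated correlation), ribosomal proteins (-0.17, 0.000941, and adjusted p = 0.573 with an estimated correlation) and fatty acid synthesis (-0.38, 0.00291, and adjusted p = 0.428 with an estimated correlation). By fry the calls of S phase (0.19), AP-1 targets (0.194) and actin genes (0.0911) were lost. The stress response (0.0298) and matrix genes (0.0302) passed by fry as higher in shJUNs. In all 536 genes were higher and 390 lower, 311 and 154 of them at least 2-fold. The genes lower numbered 235 without shHIF2A replicate 1, and the counts were 324 and 195 without shHIF2A replicate 2, and 326 and 170, 315 and 193, and 306 and 165 without shJUNs replicates 1, 2 and 3. They were 879 and 742 in a fit of those 6 libraries alone, and 844 and 633 without parental replicate 1 and shYAPTAZ replicate 1 together. The libraries did not overlap for 31.2% of genes against 10% by chance.

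Between shYAPTAZ and shHIF2A, p53 targets differed most by median and by camera with the preset correlation, with 14 of 26 lower in shYAPTAZ and 0 higher by edgeR (15 and 0 adjusted over the list alone, median -1.21, camera adjusted p = 1.26e-07, and adjusted p = 0.188 with an estimated correlation). Fry gave glycolysis a smaller adjusted p (0.000106) than p53 targets (0.000463). MGMT was 0.701 ± 0.399 CPM against 50.3 ± 4.17 CPM (74.4-fold lower, adjusted p = 3.71e-10), SHISA2 and SLC16A4 at least 85.2-fold and 72.9-fold lower, and HSPA1A, a heat shock gene with a near-identical paralog, 52.4-fold lower. ENTPD3 was at least 122-fold higher, ARTN, a neurotrophic factor, 78.9-fold, CDH11, a cadherin of mesenchymal cells, 74-fold and CENPV by a ratio of 144 (25.5 to 5740). EPAS1 was higher by 2.82 on the log2 scale (adjusted p = 7.4e-06). HIF2A targets lay higher in shYAPTAZ, with 9 called higher and 3 lower, as also adjusted over the list alone (median 0.55, camera adjusted p = 0.0251, and adjusted p = 0.486 with an estimated correlation), and YAP/TAZ targets lower, with 8 lower and 3 higher (9 and 3 adjusted over the list alone, median -0.51, camera adjusted p = 0.0264, and adjusted p = 0.188 with an estimated correlation).

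Further lists higher in shYAPTAZ than in shHIF2A were mitosis (median 0.51, camera adjusted p = 0.000941, and adjusted p = 0.631 with an estimated correlation), glycolysis (0.42, 0.0185, and adjusted p = 0.188 with an estimated correlation), S phase (0.45, 0.0227, and adjusted p = 0.722 with an estimated correlation), AP-1 targets (0.6, 0.0393, and adjusted p = 0.611 with an estimated correlation) and renal tubule markers (0.75, 0.0264, and adjusted p = 0.362 with an estimated correlation). Lists lower were mitochondrial genome transcripts (-0.56, 0.00139, and adjusted p = 0.391 with an estimated correlation), cholesterol synthesis (-0.51, 0.00291, and adjusted p = 0.53 with an estimated correlation), fatty acid synthesis (-0.36, 0.0264, and adjusted p = 0.575 with an estimated correlation) and oxidative phosphorylation (-0.26, 0.0269, and adjusted p = 0.575 with an estimated correlation). By fry the calls of mitosis (0.137), S phase (0.304) and AP-1 targets (0.125) were lost. Matrix genes (0.00269) and histones (0.0287) passed by fry as higher in shYAPTAZ, and interferon-stimulated genes (0.0112) as lower. In all 1195 genes were higher and 1073 lower (710 lower in a fit of those 6 libraries alone), and the libraries did not overlap for 32.2% of genes against 10% by chance.

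Between shYAPTAZ and shJUNs, p53 targets were again lower in shYAPTAZ, 15 of 26 with 0 higher by edgeR (17 and 2 adjusted over the list alone, median -1.17, camera adjusted p = 1.26e-08, and adjusted p = 0.188 with an estimated correlation). AUTS2 and LEF1 were at least 230-fold and 71-fold higher, PTN 272-fold at 95.4 ± 2.17 CPM, and ENTPD3 higher by a ratio of 491 (87.5 to 19400). SLC16A4 and SHISA2 were at least 84.3-fold and 62.4-fold lower, LAYN 45.8-fold and PTCHD4 by a ratio of 89.5 (24.5 to 743). Mitosis genes were higher, 9 of 30 with 0 lower by edgeR, as also adjusted over the list alone (median 0.44, camera adjusted p = 0.0122, and adjusted p = 0.722 with an estimated correlation), as were renal tubule markers (0.75, 0.0251, and adjusted p = 0.362 with an estimated correlation) and cholesterol synthesis (0.42, 0.0482, and adjusted p = 0.631 with an estimated correlation). HIF2A targets did not pass the test between these knockdowns (median 0.17, mean -0.01, camera adjusted p = 0.9), nor did YAP/TAZ targets (0.0934). By fry the calls of mitosis (0.283) and cholesterol synthesis (0.194) were lost. YAP/TAZ targets (0.00203), epithelial genes (0.000101) and interferon-stimulated genes (0.0183) passed by fry as lower in shYAPTAZ. In all 968 genes were higher and 1017 lower, and the libraries did not overlap for 33.3% of genes against 10% by chance. Without shJUNs replicates 1, 2 or 3 the genes higher numbered 627, 626 and 594.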

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

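All tests in this part were fixed in advance. Camera called 10, 12 and 4 lists in the comparisons between knockdowns, and those given here are the 4 lists that were also called against parental cells either in opposite directions, or in 1 knockdown alone with a difference from both others. No explanation was tested. None of these calls held with an estimated correlation. Glycolysis and hypoxia metabolism genes lay higher in shJUNs than in shHIF2A by a median log2 difference of 0.25 (adjusted p = 0.0283, and adjusted p = 0.188 with an estimated correlation) and higher in shYAPTAZ than in shHIF2A by 0.42 (adjusted p = 0.0185, and adjusted p = 0.188 with an estimated correlation). DNA replication and S phase genes lay higher in shJUNs than in shHIF2A by 0.49 (adjusted p = 0.000679, and adjusted p = 0.611 with an estimated correlation) and higher in shYAPTAZ than in shHIF2A by 0.45 (adjusted p = 0.0227, and adjusted p = 0.722 with an estimated correlation). By fry these S phase differences did not pass (0.19 and 0.304), and the libraries of the groups overlapped: the mean centred log2 CPM of the list was -0.76, -0.57 and 0.12 in shHIF2A, 0.05, 0.19 and 0.41 in shJUNs, and -0.45, 0.04 and 0.57 in shYAPTAZ. The p53 targets had a median log2 difference of -1.21 in shYAPTAZ against shHIF2A (adjusted p = 1.26e-07, and adjusted p = 0.188 with an estimated correlation) and of -1.17 in shYAPTAZ against shJUNs (adjusted p = 1.26e-08, and adjusted p = 0.188 with an estimated correlation). Cholesterol synthesis genes had a median of -0.72 in shJUNs against shHIF2A (adjusted p = 1.26e-08, and adjusted p = 0.208 with an estimated correlation). Groups of 3 libraries were not tested for a single library far from the others.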

How the results depend on the processing

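The runs without parental replicate 1 and shYAPTAZ replicate 1 together, without chromosomes 13, 14 and Y, and with each chromosome centred were chosen only after the results were seen. For named genes, 5126 of 5179 values under the alternatives kept direction and side of the threshold, 41 lost their call, 4 gained one and 8 reversed, and 212 of 226 gene results were unchanged in every alternative run. For the lists called against parental and the target lists not called, 33 results, 629 of 693 values kept both, 61 lost their call, 1 gained one and 2 reversed. All 226 gene results were the same with relative log expression factors, with no filter, with DESeq2 and with a fit that was not robust. Where a call changed the cause was not tested, except that fewer libraries or counts, by their construction, give less power.

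At 2-fold or more, genes higher and lower numbered 576 and 634 in shHIF2A, 706 and 547 in shJUNs, 982 and 854 in shYAPTAZ, 311 and 154 in shJUNs against shHIF2A, 752 and 502 in shYAPTAZ against shHIF2A, and 537 and 544 in shYAPTAZ against shJUNs. Shared falls were then 265 for shHIF2A and shJUNs, 265 for shHIF2A and shYAPTAZ, 239 for shJUNs and shYAPTAZ and 168 for all 3, and shared rises 288, 284, 386 and 179. A fit on the 6 libraries compared gave 879 higher and 742 lower for shJUNs against shHIF2A and 710 lower for shYAPTAZ against shHIF2A. Without parental replicate 1 and shYAPTAZ replicate 1 together shJUNs against shHIF2A had 844 and 633. Camera with an estimated correlation called 0 lists in each of the 6 comparisons.

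Leaving out 1 library gave 772 to 1408 genes higher in shHIF2A, 846 to 1450 higher and 672 to 1251 lower in shJUNs, 306 to 694 higher and 165 to 505 lower in shJUNs against shHIF2A, and 594 to 1082 higher in shYAPTAZ against shJUNs. Shared falls ranged from 360 to 649, 335 to 561, 363 to 610 and 227 to 391 (all 3), and shared rises from 385 to 754 (shHIF2A and shJUNs), 380 to 658 (shHIF2A and shYAPTAZ) and 240 to 436 (all 3). The lowest count of genes higher in shHIF2A, 772, came without parental replicate 1. Lists called in shYAPTAZ against shJUNs ranged from 2, without shJUNs replicate 2, to 6.

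Values that reversed belonged to results that had not passed. Without 1 library, the adjusted p of the AP-1 targets ranged from 0.642 to 0.972 in shJUNs (reversed without shJUNs replicate 2, 0.927) and from 0.213 to 0.817 in shYAPTAZ (reversed without shYAPTAZ replicate 3, 0.747). The log2 change of JUNB in shHIF2A ranged from -0.63 to 0 (reversed without parental replicate 3). That of JUN in shYAPTAZ ranged from -0.1 to 0.22 (-0.05, -0.1 and -0.09 without parental replicate 1, shYAPTAZ replicate 2 and shYAPTAZ replicate 3). That of JUNB in shYAPTAZ ranged from -0.29 to 0.34 (-0.29, -0.03 and 0 without parental replicate 1, shYAPTAZ replicate 1 and shYAPTAZ replicate 3), and was -0.34 without parental replicate 1 and shYAPTAZ replicate 1 together.

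The replicate numbers were tried as a block, since numbers 1 and 3 correlated best with their own number in every pair of groups, although number 2 did not. With the block genes higher and lower numbered 1513 and 1365 in shHIF2A, 1564 and 1329 in shJUNs and 1781 and 1727 in shYAPTAZ, and no named gene changed its call. Among lists, the mitochondrial genome transcripts in shYAPTAZ against parental gained a call with the block (adjusted p = 0.0497, from 0.0555), and between knockdowns the histones in shYAPTAZ against shHIF2A did (0.0348, from 0.0623). The numbers were not taken as pairs. Depth limits falls to a floor of 3 counts over a group, and planted 2-fold changes were recovered in 35.8% of genes. That simulation held far fewer changed genes than were called here, which makes the adjusted threshold stricter. Its share is therefore not the recovery in these data.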

Other observations

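The genes in these first 2 paragraphs were chosen after their values were seen. HIF1A, the gene of the other main HIF alpha subunit (ENSG00000100644, chromosome 14, 61695513 to 61748259), was 6.14 ± 2.27 CPM in parental cells and 137 ± 20.2 CPM in shYAPTAZ, 22-fold higher (edgeR adjusted p = 1.25e-10), where chromosome 14 genes had a median rise of 1.83-fold. It was 11.5 ± 2.65 CPM in shHIF2A (adjusted p = 0.0405). Also in shYAPTAZ, CTHRC1, a secreted protein of matrix remodelling, rose 41.1-fold from 21.8 ± 4.15 CPM to 902 ± 221 CPM (adjusted p = 1e-13), and MMP2, a matrix metalloproteinase, 56.4-fold to 471 ± 167 CPM (1.42e-13). GSTP1, a glutathione transferase, fell 15.7-fold to 17.8 ± 7.97 CPM (2.86e-11), and EDA2R, a receptor of the TNF family, had 203 parental counts and 3 in shYAPTAZ (9.72e-08). MDM2, a ubiquitin ligase, fell 2.83-fold (0.00104). The cancer-testis genes MAGEA3 and MAGEA12, which have close paralogs, had no parental count and reached 14.1 ± 5.92 CPM and 8.72 ± 3.88 CPM in shYAPTAZ. Genes with at least 5 CPM in 1 group and 3 counts or fewer over the other numbered 72 switched on and 35 off in shYAPTAZ, 21 and 11 in shJUNs, and 5 and 1 in shHIF2A.

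In all 3 knockdowns ZHX2, a transcription factor known as a VHL substrate, fell 11.1-fold, 6.97-fold and 1.97-fold in shHIF2A, shJUNs and shYAPTAZ (adjusted p = 9.26e-06, 3.92e-05 and 0.0399). ERRFI1, an inhibitor of EGF receptor signalling, fell 14.7-fold, 8.67-fold and 5.16-fold (adjusted p = 5.51e-12, 1.05e-10 and 1.9e-09), and CDH6, a cadherin of kidney tubules, rose 4.05-fold, 3.07-fold and 5.25-fold (adjusted p = 0.00285, 0.00909 and 0.000636). Markers of other cell types were too few for a list test: 2 of blood cells, 1 of endothelium and 4 of neurons were measured. CD74 was 4.36 CPM in parental cells and 10.0, 55.3 and 15.7 CPM in shHIF2A, shJUNs and shYAPTAZ, and LAPTM5 had 1 parental count and reached 12.7 CPM in shYAPTAZ (adjusted p = 0.000153). EGFL7, of the endothelial list, fell 4.48-fold in shYAPTAZ (3.43e-05). Of the neural markers, NEFL, a neurofilament chain, rose 5.4-fold, 2.48-fold and 8.66-fold in shHIF2A, shJUNs and shYAPTAZ from 257 ± 84.9 CPM (adjusted p = 5.03e-07, 0.000193 and 1.59e-08). SNAP25 and MAP2 rose in shYAPTAZ (6.16e-05 and 0.0372) and in shHIF2A (0.0431 and 0.00728) and did not pass in shJUNs (0.0568 and 0.0576). UCHL1 fell 2.54-fold in shYAPTAZ (1.73e-05) and did not pass in shHIF2A (0.279) or shJUNs (0.306).

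Tests chosen only after the result was seen were those of simulated shared controls, of a single parental library, of the replicate numbers and of the order of depths, and of the splits of the libraries. Chromosome 14 lay higher in shYAPTAZ by a median of 0.87 on the log2 scale, with 0.88, 0.79 and 0.75 in its replicates. A trend with GC content is argued against, since 98.9% of the median was left after a loess fit on GC. The rise was spread along the chromosome, with 100% of its 9 windows of 10 Mb above the set share of the chromosome median (0.76 to 1.08), which is what more copies of chromosome 14 in this line would give. That remains a hypothesis, since copy number was not measured, and whether such a difference arose before or after the knockdown stays open. An effect of YAP and TAZ on this chromosome's genes was not tested.

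The genes called in all 3 knockdowns numbered 742 in both directions. Noise of the shared parental libraries as the whole cause is argued against, since simulated knockdowns with independent changes and shared controls had on average 1.92 (lower) and 1.91 (higher) times as many genes in all 3 as independent lists, with 17 and 25 genes at most, against 29.5 and 24 times and 351 and 391 genes observed. That 1 aberrant parental library is the cause of the whole set is argued against too, since 423 of the 742 were called in all 3 in the same direction without parental replicate 1, and 498 and 588 without replicates 2 and 3. Part of the set may still rest on parental replicate 1, and the bound of this test was set after the result was seen. A common response of equal size in every derived line, for example to shRNA expression or drug selection, could not be excluded: 31.5% of these genes, 234, differed between at least 2 knockdowns, against 27.5% of all genes tested, and no line with a control shRNA was analysed. The lower EPAS1 level in shJUNs and shYAPTAZ could carry part of the falls. EPAS1 fell further in shJUNs than in shYAPTAZ, so falls that follow its level would be larger in shJUNs. The genes lower in shHIF2A had close median log2 changes in both, -0.72 in shJUNs and -0.69 in shYAPTAZ. For the genes lower in shHIF2A, the median log2 ratio of shYAPTAZ over shJUNs, less the median of all genes, was 0.04. Its 95% bootstrap interval, over genes and not libraries, was 0 to 0.08 (camera p = 0.37, and p = 0.639 with an estimated correlation). This value lies between the bounds set for either answer. Chromosomes 14, 16 and 22 lay higher and chromosome 15 lower in both shJUNs and shYAPTAZ. Of these only chromosome 15 passed in shHIF2A (median -0.14). How far such shifts add to the shared calls was not tested. A shared dependence of these genes on HIF2A, AP-1 and YAP/TAZ stays open as well.

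The mitochondrial share of counts was highest in replicate 1 and lowest in replicate 3 of every group. Over 12286 genes outside the mitochondrial genome, deviations from the group means correlated between libraries with the same number at a mean r of 0.066, across genes, which are not independent replicates, against 0.06 at most under the other pairings of the numbers (exact permutation p = 0.00463 over 216 arrangements, the smallest they can give). Depth is argued against, since at most 1 group had any given order of depths. The replicate number may mark shared handling of the libraries, a hypothesis found on the same data, for which no biological explanation was tested.

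The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. In fits of those 6 libraries alone the real splits called 2193, 2805 and 2263 genes in shHIF2A, shJUNs and shYAPTAZ against parental, 1621 in shJUNs against shHIF2A, 1627 in shYAPTAZ against shHIF2A and 1857 in shYAPTAZ against shJUNs, and the highest other split called 0 in each by edgeR, with 1 split, the real one, as large. Of 100 groupings of the 12 libraries into 4 groups, 1, the real one, called as many as 4759 genes and the highest other called 433. No other grouping tried thus reached the number called. The other groupings mix libraries of different lines, so this speaks neither to any single gene nor to why the lines differ.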
